A study of Homo sapiens with 2 samples.

How the data were processed

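The series held 2 libraries of 1 pool of OVCAR5 cells, a gene expression library and a hashtag library, per the labels. Cells were partitioned on the Chromium Controller and prepared as 3' gene expression and Cell Hashing libraries, per the labels' protocols. The deposited values are raw UMI counts per feature and barcode, not normalised. The matrix was written by Cell Ranger 5.0.1, per the file headers, while the submitters' processing notes name Cell Ranger 2.1.1 and GRCh38. This difference was not resolved. The deposited identifiers are Ensembl gene IDs with symbols and 8 hashtag names that carry no condition. The lowest barcode total was 500 UMIs, and how barcodes were called is not given in the sources used here.

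Cells with at least 500 genes and at most 20% mitochondrial UMIs were kept. The filter removed 603 barcodes, 361 of them under the gene minimum and 576 over the mitochondrial limit. HTODemux in Seurat 5.3.0 (R 4.3.3, centred log-ratio over cells, quantile 0.99) was the planned hashtag assignment. It called 293 single cells, 6800 cells with several hashtags and 108 with none, because most cells carried 2 hashtags by construction. Pairs were therefore read instead, a rule added after the data were seen: the second hashtag had to hold at least 5 times the third plus 1 UMI, and a pair needed at least 100 cells. The rule is meant to remove cells of several pairs, and 1087 cells failed it. Doublets of cells from the same pair cannot be seen by hashtags, and no other doublet caller was run.

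UMIs were summed per pair and divided by the pair's total to give CPM, with exact Poisson intervals and exact conditional intervals of ratios at 95%. A span is the highest over the lowest pair, with the lowest count set to at least 3. Free RNA was not subtracted, so the lowest levels may include it. The highest and lowest of 18 values differ by chance, so 20 Poisson draws from the pooled profile give the span from counting noise alone. These draws leave out variation between cells, such as UMIs concentrated in few cells. Exact Clopper-Pearson intervals were used for shares. For shares and list correlations each cell was thinned to 10000 UMIs, which kept 6997 of 7201 cells. Clusters came from scanpy 1.11.5 and leidenalg 0.10.2 (2000 variable genes, 30 components, 15 neighbours, resolution 0.5). List correlations were set against 100 random lists matched on mean expression. Python 3.11.15, numpy 2.4.6 and scipy 1.17.1 were used.

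The planned tests of dose, time, gene list trend and freezing (edgeR and permutation) were not run, because no map from hashtags to conditions was at hand, and conditions were not inferred from expression. The gene lists, cell filter, clustering settings and the rule for named genes were fixed before the data were examined. That rule takes the 10 genes with the largest fold per cluster among those with at least 100 UMIs, the 25 genes with the largest excess variance, and 2 to 4 members of 7 interferon lists by mean level. JAK1, JAK2, the cell type markers and the interferon, keratin and other genes named for cluster 11 or in the closing part were named outside it, some after their values were seen. The counts over lists include 1 gene that is not reported here. IRF1 was taken as the example for the alternatives and tests on pairs after its values had been seen.

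The calculations were tested on simulated data. The pair rule returned 99.98% of 5000 simulated cells to their pair and left 93.4% of 1000 simulated multiplets without one. Simulated cells carried a small fixed share of the other hashtags. In real cells the third hashtag held 19.5% at the 95th percentile, so the 99.98% speaks only for cleanly labelled cells. Spans were tested only in genes with at least 2000 UMIs. Of 50 such genes changed 4-fold in 1 pair, 100% had that pair highest, and 0 of 7366 unchanged genes spanned 4-fold. Simulated lists raised in the same cells gave a rho of 0.732, and in different cells -0.018. Alternatives covered the cell filter, the hashtag rule, thinning, clustering settings and the removal of small clusters.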

Results

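OVCAR5 cells, an ovarian carcinoma line carrying a reporter for interferon-gamma sensing, were profiled by droplet single-cell RNA sequencing with antibody hashtags. The labels name 18 conditions in 1 pool: cells left unstimulated or given interferon-gamma at 1, 10 or 100 ng/ml for 2, 6, 12 or 24 h, plus frozen cells of the 24 h unstimulated and 100 ng/ml conditions. The deposited matrix held 7804 barcodes, 36601 genes and 8 hashtags, with 246744793 gene UMIs and 14124227 hashtag UMIs. After filtering, 7201 cells remained, with a median of 31206 UMIs, 5584 genes and 11.2% mitochondrial UMIs per cell. No source used here ties a hashtag to a condition, so no dose, time or freezing comparison was made. The data were treated as 1 pooled sample, and every interval below covers counting error only.

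The cells were labelled by combinations of hashtags. In the median cell the most abundant hashtag held 54.9% of hashtag UMIs, the next held 39.7%, and the one after held 0.984%. A pair of hashtags could be read in 6114 cells (84.9%, exact 95% binomial interval 84.1 to 85.7%). These cells fell into 18 of the 28 possible pairs, with 166 to 493 cells per pair (median 332). The other 10 pairs held 0 of 6114 cells, which allows a share of up to 0.0491%. Median depth per pair ran from 27824.5 to 32945 UMIs per cell. The 1087 cells without a pair had a median of 51617 UMIs, and 959 of them carried at least 3 hashtags over the cut-offs. The standard assignment to single hashtags kept 293 cells and was not used further.

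Interferon-response genes differed widely in level between the 18 hashtag pairs. Among transcription factors, 13 of 17 spanned at least 4-fold from the lowest to the highest pair. IRF1, an early interferon-responsive activator, ran from 43.7 to 1357 CPM (UMI counts scaled to a common total), a 31.0-fold span (interval 28.2 to 34.3). The 2 nuclear body proteins SP100 and SP110 spanned 4.01-fold and 7.68-fold. The pair with the highest IRF1 (hashtags 1 and 6) had 23.1 CPM of CD74, against 1278 CPM in the pair of hashtags 7 and 8. With counting noise alone, 20 simulated draws gave at most 0 transcription factors with such a span.

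Antigen presentation genes were among those with wide spans. In the MHC class II list 14 of 15 members spanned 4-fold, with a median span of 50.2-fold. CD74, the invariant chain, ran from 16.003 to 1278 CPM, and HLA-DRA from 3.07 to 254 CPM, a span of 82.7-fold (55.5 to 129). The low ends of these spans may include free RNA, which the intervals do not cover. IFI30, a lysosomal reductase, spanned 6.42-fold. In the MHC class I list 13 of 19 members spanned 4-fold. B2M, the class I light chain, spanned 3.38-fold and the proteasome activator subunit PSME2 6.54-fold, while the chaperone CALR spanned 1.35-fold. The span of HLA-DRA was 288-fold when each cell was thinned to 10000 UMIs, resting on 3 UMIs in the lowest pair, and at least 223-fold under the stricter cell filter, with 2 UMIs there.

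Wide spans also lay in the chemokine, guanylate-binding protein and checkpoint lists. Of 11 chemokines with at least 100 UMIs, 10 spanned 4-fold. CXCL10, a ligand of CXCR3, ran from 2.56 to 315 CPM, CXCL11 from 1.41 to 211 CPM and CXCL9 from 0.185 to 68.4 CPM. All 6 measured guanylate-binding proteins spanned 4-fold, GBP1 by 79.3-fold and GBP4 by 92.6-fold. In the checkpoint list 7 of 11 did so. IDO1, which degrades tryptophan, ran from 24.1 to 4298 CPM (179-fold, interval 155 to 207), and WARS, the cytosolic tryptophanyl-tRNA synthetase, spanned 35.3-fold. CD47 spanned 2.85-fold. The CXCL10 span was 123-fold, and 264-fold with each cell thinned, where it rested on 4 UMIs in the lowest pair. The 369-fold span of CXCL9 rested on 3 UMIs in the lowest pair, and thinning left 0 there, so that its 51.5-fold is only a lower bound.

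**Figure D1:**
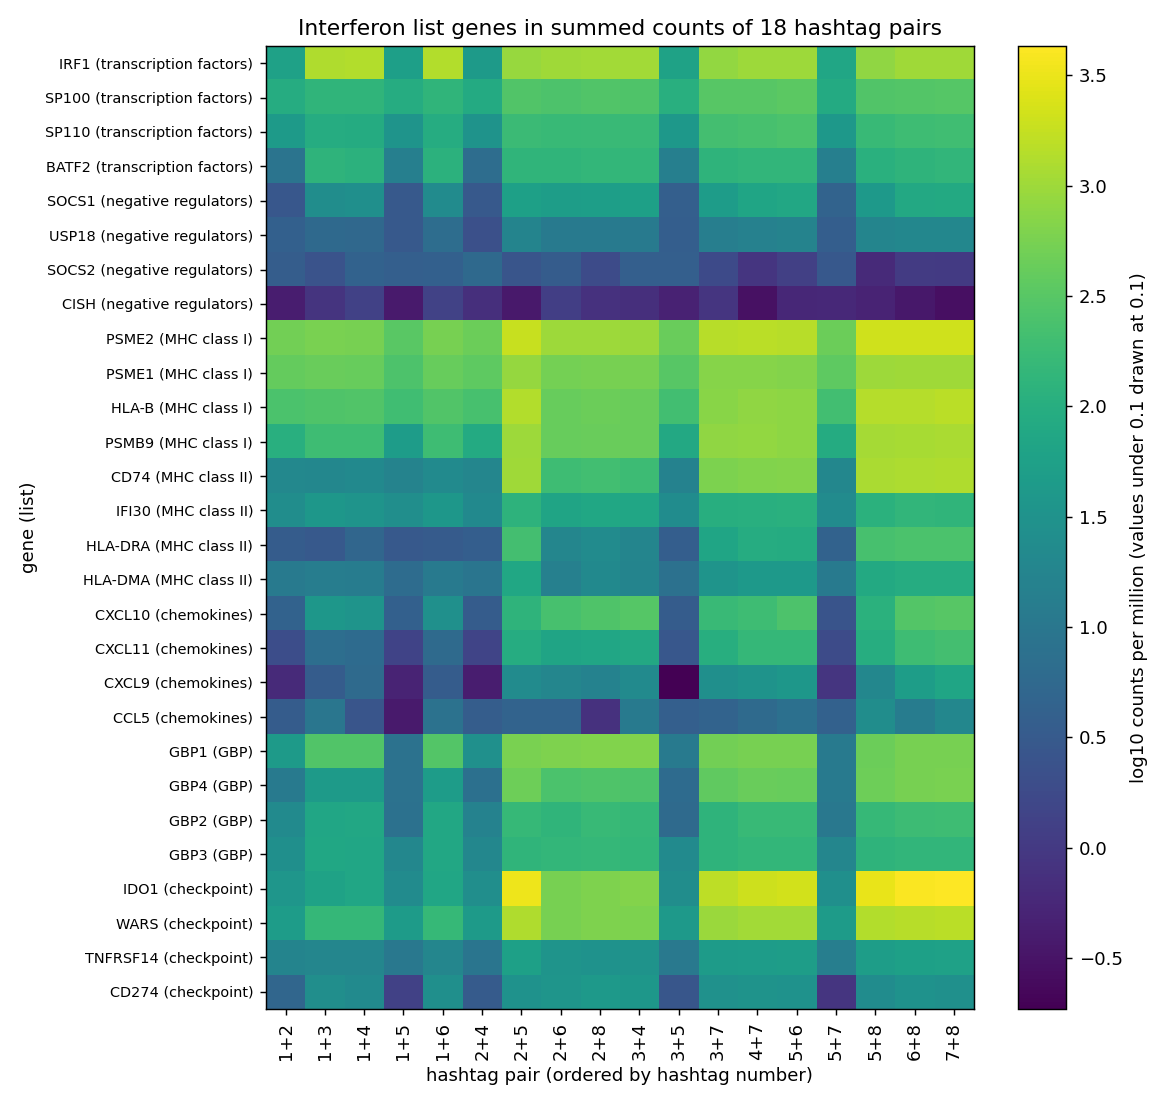
Levels of interferon list genes in summed counts of each hashtag pair. Columns are the 18 pairs ordered by hashtag number, rows are up to 4 genes per list with a span of at least 4-fold, and colour is log10 CPM. IDO1 reached 4298 CPM in the pair of hashtags 7 and 8.

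Negative regulators were mixed. Of 9 members, 4 spanned 4-fold. SOCS1, an inhibitor of JAK kinases, ran from 2.82 to 83.6 CPM (29.7-fold), while the phosphatases PTPN1 and PTPN2 spanned 1.55-fold and 1.42-fold. Among 7 receptor and kinase genes only JAK2 spanned 4-fold (7.08-fold), and JAK1 spanned 1.14-fold. Antiviral genes reached 4-fold in 24 of 36 members, cell death genes in 9 of 20 and NF-kB targets in 7 of 15. None of 28 S phase, 32 G2/M phase, 13 mitochondrial or 12 housekeeping genes did so.

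Summed cholesterol synthesis genes were 2.54-fold higher in the highest pair (hashtags 1 and 3) than in the lowest, and 7 of 14 members spanned 4-fold. The growth arrest sum spanned 1.64-fold, with 5 of 12 members at 4-fold, and the hypoxia and glycolysis sum spanned 1.499-fold, with 5 of 15. Stress genes reached 4-fold in 6 of 16 members, the unfolded protein list in 2 of 11, epithelial genes in 5 of 13 and mesenchymal genes in 3 of 9. Draws with counting noise alone reached up to 3 mesenchymal genes, as many as observed. They reached 2 each in the MHC class II and growth arrest lists, and at most 1 in any other list. CCN2, a matricellular protein, ran from 8.72 to 449 CPM, highest in the pair of hashtags 1 and 2. Across all 7566 genes with at least 2000 UMIs, 261 spanned 4-fold, against 0 in simulated draws with counting noise alone. With at least 100 UMIs 2021 of 13921 genes did, against a median of 503.5 and at most 539 in those draws. The draws leave out variation between cells, so both counts are set against counting noise only.

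**Figure D2:**
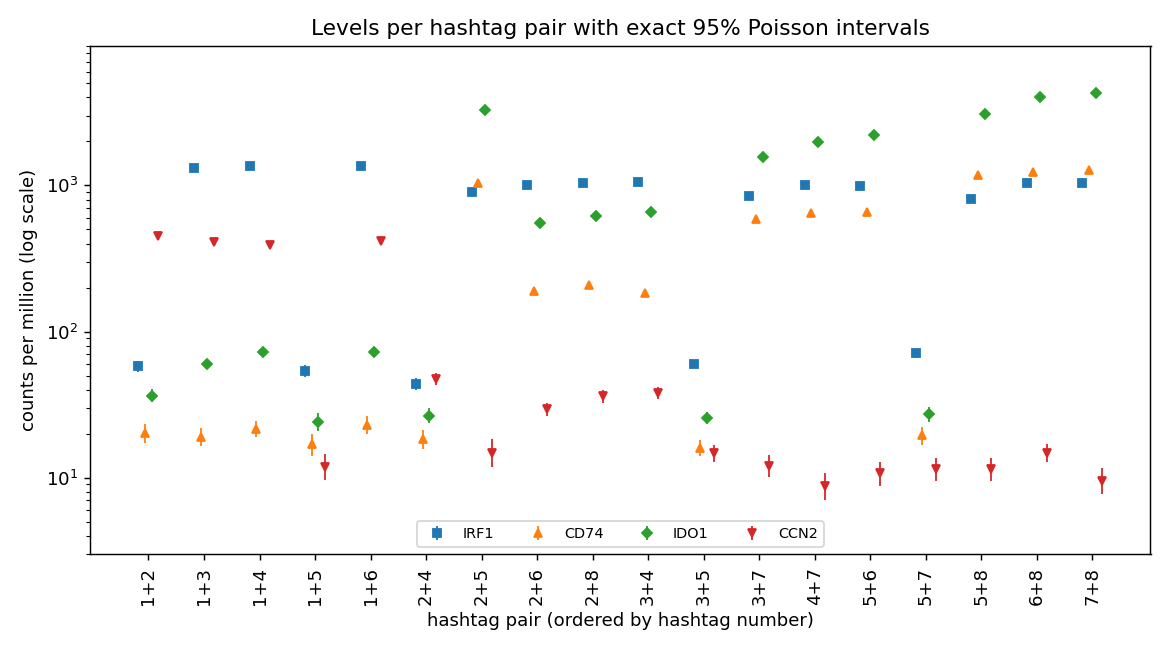
CPM of 4 genes in each hashtag pair, on a log axis, with exact 95% Poisson intervals as bars. IRF1 ran from 43.7 to 1357 CPM over the 18 pairs, and IDO1 from 24.1 to 4298 CPM.

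The share of cells with a chemokine transcript differed between genes and pairs. With each cell thinned to 10000 UMIs, CXCL9 had a UMI in at most 24.6% of the cells of a pair (interval 20.2 to 29.5%, 39.0% unthinned) and CXCL10 in at most 47.7% (43.0 to 52.4%, 59.4% unthinned). The lowest pairs had 0% (upper limit 1.54%, 1.65% unthinned) and 1.27% (10.3% unthinned). CXCL11 had a UMI in 58.8% of cells in its highest pair (53.4 to 64.1%, 75.6% unthinned) and 1.23% in its lowest (5.39% unthinned). Free RNA was not subtracted and thinning drops UMIs, so these are shares of cells with a UMI and not of cells expressing the gene. HLA-DRA reached 80.2% of cells in its highest pair (92.2% unthinned) and 0.935% in its lowest (8.53% unthinned). IDO1 ran from 18.1% (55.2% unthinned) to 100%. The tenth of cells with most CXCL10 held 59.2% of its UMIs in its highest pair. Thinning left out 158 of 6114 paired cells, 5 to 19 per pair.

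The pooled cells formed 12 clusters, some led by cell cycle genes and others by different genes. Several followed hashtag pairs, and clusters 1 and 2 had cells of only 10 pairs. Cluster 3 had 184, 169, 212 and 158 of its 751 paired cells in the pairs of hashtag 1 with 2, 3, 4 and 6. Cluster 4 had 219, 215 and 198 of 665 in hashtags 3 and 4, 2 and 6, and 2 and 8. Folds against all other cells thus also hold differences between pairs. Clusters 1 and 5 were led by replication-dependent histone genes such as HIST1H1A, HIST1H1B and HIST1H1D, and cluster 7 by the mitotic genes PIF1, NEK2 and AURKA. Cluster 9 was led by SHISA3, NEURL1B and TNFAIP8L1, with PIF1, CENPE and FAM83D among its top 10. MHC class II genes were 2.64-fold higher in cluster 1 than in all other cells. Cluster 2 was led by CCL25, HLA-DQA2 and EXOC3L1, and its MHC class II genes were 2.65-fold higher. Cluster 3 was led by TCIM, GPR183, CCN2 and EDN1, cluster 4 by H19, TNIP3 and CCL7, and cluster 6 by AXIN2. Cluster 8 held 626 cells, 76.2% of them without a hashtag pair, at a median of 49247.5 UMIs. Cluster 12 held 116 cells at a median of 1833 UMIs. The number of clusters was 7 at the lower clustering resolution.

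Clusters 10 and 11 were small and occurred in all 18 pairs. Cluster 10 held 296 cells (4.11%, interval 3.66 to 4.59%) and was led by CCL5 (71.0-fold over other cells), HERC5 (56.6-fold), RSAD2 (40.9-fold) and OASL (33.6-fold), which belong to the antiviral response, with IL6 16.8-fold higher. Cluster 11 held 191 cells (2.65%, interval 2.29 to 3.05%). SERPINB3 had 10 UMIs in all other cells and was 1782-fold higher in cluster 11 (interval 963 to 3733). ZFHX4, PCSK1N, TFPI2 and SERPINB4 were also among its leading genes. Its median mitochondrial share was 5.18% and its median depth 44781 UMIs.

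**Figure D3:**
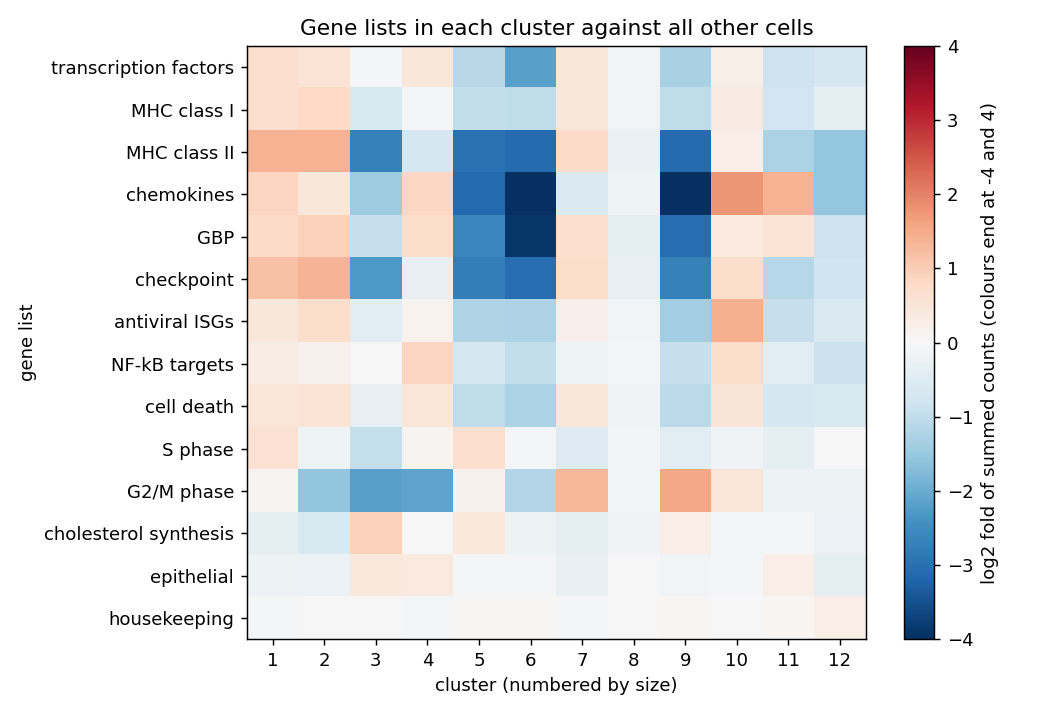
Summed counts of 14 gene lists in each cluster against all other cells. Columns are clusters numbered by size and colour is the log2 fold. MHC class II genes were 2.65-fold higher in cluster 2, which had cells of only 10 of the 18 pairs.

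Genes whose variance most exceeded the trend were led by IDO1, with an excess of 1.87 on the natural-log scale. CD74, WARS, IRF1 and PLAAT4 followed. The 25 genes also included the proliferation genes HIST1H4C, UBE2C, TOP2A and CENPF, and NNMT, AREG, CYP1B1, KRT19, AKAP12 and FABP4. Of the epithelial genes, KRT18 was found in 99.9%, KRT8 in 99.4%, KRT7 in 94.5%, KRT19 in 82.3%, EPCAM in 69.6% and CDH1 in 1.78% of cells. CDH1 stood at 31.0 CPM in cluster 11 and at most 0.156 CPM in any other cluster. The mesenchymal gene VIM was in 99.7% of cells, at 2521 CPM. CD3E, IFNG and TYROBP had 0 UMIs and PTPRC had 2. COL1A1 had 165, and no member of the T cell and endothelial lists reached 100 UMIs over the paired cells. TRBC2, which is outside these lists, had 764 UMIs in paired cells of cluster 11 and 26 in other paired cells. In the myeloid list CD68, CD14 and LYZ had 6913, 1121 and 105 UMIs over all cells, in 54.5%, 13.4% and 1.37% of them.

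Several interferon list totals rose together from cell to cell. Across all cells Spearman's rho between MHC class I and MHC class II totals was 0.819, where random lists matched on expression gave at most 0.148 at their upper 97.5% limit. Within single pairs the rho was lower, with a median of 0.360 (range 0.129 to 0.562). MHC class I and antiviral totals gave a median of 0.579 within pairs, from 0.487 to 0.699. Within pairs, negative regulators stayed inside the random range with some lists: with MHC class II the median was 0.0308, inside the -0.0594 to 0.0528 of random lists, and with MHC class I it was 0.0522, against up to 0.0637. Antiviral and G2/M totals gave a median of -0.275, and the value was negative in all 18 pairs (-0.481 to -0.171). Cells are not replicates, so no p-value was computed.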

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

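The tests of doublets and depth in cluster 11, its looser cut-offs, and the tests of doublets and free RNA in cluster 10, the latter in place of earlier comparisons of RSAD2 and then of the antiviral list with other cells, which could decide nothing, were chosen, like all tests on IRF1, after the results were seen. Both sets of barcodes outside the pair comparison carried interferon-response transcripts, above the limit that a count of 0 allows. IDO1 stood at 1506 CPM of non-mitochondrial UMIs in the 603 barcodes that failed the filter, and at 1291 in the 1087 cells without a hashtag pair. Free RNA alone would pass that limit, so these values show that the transcripts were present and nothing on their origin.

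Cluster 11 held genes that other cells lacked; its median of 44781 UMIs argues against low-quality barcodes. The sum of its 28 high genes had a median 6.18 times that of the highest of 5995 other paired cells. Doublets of those cells would not exceed that highest value. Yet the 28 genes were chosen in the same cells, at 100 CPM or more and at least 20-fold higher in cluster 11. The excess was thus largely built in, and this comparison cannot decide on doublets. Cells with 3 or more hashtags made up 29.8% of the cluster (interval 23.5 to 36.9%), more than the 13.9% of all cells. That share is under the 50% set for doublets between pairs. Cells of another line may have been mixed in, and the test of that set beforehand went against it: of 1501 genes at 100 CPM or more in other paired cells, 0 were at least 20-fold lower in cluster 11. Free RNA may blunt so strict a limit. At 10-fold, chosen only after that 0, 26 of them were lower, against at most 10 in other clusters. This fell short of the 5 times that the rule asked for. The 10 were in cluster 6, while clusters 3, 5 and 9 had 6 to 7 and the others counted had 1 each. Cluster 6 had 182, 179, 152 and 112 of its 673 paired cells in single pairs, so its count may also hold differences between pairs. Of 5590 genes at 20 CPM or more, 17 were 20-fold lower (at most 16 elsewhere) and 89 were 10-fold lower (at most 29). The origin of these cells stays open, and no biological explanation was tested.

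Cluster 10 held antiviral genes in each pair. Doublets between pairs were not the source, since 14.2% of its cells carried 3 or more hashtags, against 13.9% of all cells. Free RNA would not lift cells above its own level, yet the antiviral list was in every pair at least 1.62 times its level in the highest of 3 pools taken for free RNA (all barcodes, those that failed the filter and those under the gene minimum). The upper end of the ordinary response stays open: the GBP list was 1.39-fold higher in cluster 10 (median over pairs), between the limits set for and against it. Pairs differed here, with 1.98-fold to 4.69-fold in the 5 pairs of lowest IRF1 and 1.03-fold to 1.79-fold in the others. Transcripts of IFNB1, IFNL1, IFNL2 and IFNL3 together were 296-fold higher in the cluster (54 UMIs, from 7 of its 296 cells, against 4), so local production of type III interferon is a candidate explanation, with no stimulus compared.

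IRF1 differed in steps between pairs. Counting noise did not account for it, since 20 draws gave at most 1.06-fold. The span was 31.261-fold with cells thinned to 10000 UMIs. CPM already divides by a pair's total, so thinning could hardly lower the span and cannot decide on depth. Median depth per pair ran from 27824.5 to 32945 UMIs per cell. The span was 32.2-fold with the second hashtag at least 10 times the third, and 31.332-fold without clusters 11 and 12. The dose, duration and freezing of the cells, which the labels name, stay open as untested, because no pair could be tied to a condition.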

How the results depend on the processing

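All alternatives to the pair rule, the removal of small clusters, and the strict filter and thinning on pair values were chosen after seeing the data. So were the clustering of only cells with a pair and all alternatives for the count of genes spanning 4-fold. HTODemux kept 575 single cells with no cell filter and 246 with the stricter filter, and 13 cells had a top hashtag of at least 5 times the next. The share of cells with a pair was 81.1% with the second hashtag at least 10 times the third, 80.6% with exactly 2 hashtags over the HTODemux cut-offs and 75.6% with the stricter cell filter. The pooled cells gave 7 clusters at resolution 0.25 and 9 to 18 under the other settings, and at least 76.3% (cluster 10) and 97.3% (cluster 11) of cells stayed together as Jaccard overlap. The span of IRF1 stayed between 30.8-fold and 33.4-fold, and the genes spanning 4-fold numbered 261 to 330. The rho between MHC class I and class II totals stayed between 0.800 and 0.859 over all cells. Its median within pairs moved from 0.360 to 0.435 without thinning and 0.485 with the stricter filter, and that of antiviral and G2/M totals from -0.275 to -0.379 without clusters 10 to 12. Of 140 recomputed spans of 20 other genes, 120 stayed within the counting interval of the reported span. Among those that moved were CXCL10 (264-fold when thinned, on 4 UMIs in the lowest pair, against 123-fold), CXCL9, HLA-DRA and CIITA (24.0-fold when thinned, against 98.1-fold). CXCL8 moved from 69.3-fold to 28.2-fold without clusters 11 and 12, with 4 UMIs in the lowest pair. With the stricter filter it was 233-fold, with 3 UMIs there. FABP4 moved from 36.7-fold to 75.7-fold with that rule of 10 times. Thinned CXCL9 and CIITA had 0 UMIs in the lowest pair, as had CIITA with the stricter filter (26.9-fold). Those spans are lower bounds set by the minimum of 3 UMIs. Some spans that stayed within the counting interval were such bounds too. They included CXCL9 with the rule of 10 times and with the stricter filter, and CIITA without clusters 11 and 12. Thinned CD274, CXCL8 and ETV7 were further cases. Cluster 11 held most CXCL8 UMIs of the paired cells (2325, against 486 in the others), which its removal took out. The cause of the other moves was not tested. Values per single hashtag could not be had with the rule of 5 times the next, which left 13 cells. The alternatives for the dose, time and freezing comparisons were not run, since those comparisons were not made. No paired analysis was possible because the result comes from no test. Genes with few UMIs in the lowest pair limit the precision of wide spans.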

Other observations

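Cluster 11 differed in epithelial and other genes, named here after their values were seen. KRT81, a type II keratin, stood at 5672 CPM in its paired cells and 3.30 CPM in other paired cells. LDHB had 691 CPM against 0.416, S100A9 608 against 0.427 and the cell cycle inhibitor CDKN2A 192 against 0.124. CDH1, the epithelial cadherin, had 31.0 CPM in cluster 11 and EPCAM 277 CPM, against at most 0.156 and 58.7 CPM in any other cluster. TWIST1 and CDH2 of the mesenchymal list had 26.0 and 12.9 CPM there, against at most 0.0814 and 0.277 CPM elsewhere. The epithelial KRT8 (769 CPM) and the mesenchymal VIM (765 CPM) were lower in cluster 11 than in any other cluster. CYBA had 15.2-fold and CTNNA1 18.8-fold lower levels in cluster 11. CXCL8 was 456 CPM there and 2.63 CPM in other paired cells.

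Within pairs, cells of cluster 10 carried more chemokine transcripts (median 3.16-fold) and NF-kB targets (median 1.62-fold) than the other cells, while MHC class II genes were at 1.14-fold. IFNL1 and IFNL3 had 22 UMIs each in cluster 10, in 5 cells each, and IFNB1 had 0. Cluster 10 made up 1.88% to 6.84% of the cells of a pair.

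IRF1 and CD74 values over the 18 pairs fell into separate ranges, which parted the pairs in different places. IRF1 was 43.7, 53.6, 57.9, 60.4 and 70.8 CPM for hashtags 2 and 4, 1 and 5, 1 and 2, 3 and 5, and 5 and 7. After a gap of 11.4-fold it was 808, 841, 894, 995, 1004, 1012, 1032, 1044, 1046 and 1058 CPM for hashtags 5 and 8, 3 and 7, 2 and 5, 5 and 6, 4 and 7, 2 and 6, 6 and 8, 7 and 8, 2 and 8, and 3 and 4. It was highest, at 1322, 1349 and 1357 CPM, for hashtags 1 and 3, 1 and 4, and 1 and 6. The gap before these 3 pairs was only 1.25-fold, near the 1.23-fold gap inside the lowest range. CD74 was 16.003, 16.9, 18.4, 19.1, 19.5, 20.1, 21.6 and 23.1 CPM for hashtags 3 and 5, 1 and 5, 2 and 4, 1 and 3, 5 and 7, 1 and 2, 1 and 4, and 1 and 6. A gap of 7.93-fold led to 183, 190 and 208 CPM for hashtags 3 and 4, 2 and 6, and 2 and 8. A further gap of 2.85-fold led to 592, 650 and 660 CPM for hashtags 3 and 7, 4 and 7, and 5 and 6. The last 4 pairs had 1039, 1183, 1245 and 1278 CPM, for hashtags 2 and 5, 5 and 8, 6 and 8, and 7 and 8.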
